A study of Mus musculus with 8 samples.

How the data were processed

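Total RNA of the tibialis anterior was sequenced with a stranded library kit in 8 C57BL/6J mice aged 24 months, 4 K320E-skm and 4 wild-type, per the labels. The values used were FPKM per gene, deposited by the authors in 1 table of 48328 Ensembl genes by 8 libraries. FPKM are fragment numbers divided by the length of the transcript and by the number of mapped fragments of the library. Per the submitters' processing notes, CASAVA, TopHat2 2.0.10 and Cufflinks 2.1.1 were used with the genome build mm10. The annotation release, the strand setting, the bias correction and the handling of ribosomal RNA are not given in the sources used here. Because FPKM are relative to all mapped fragments, a gene group that takes more of a library lowers the values of all other genes in it. Cufflinks divides fragments among overlapping genes, so values of overlapping genes, paralogs and very short genes are uncertain, and an exact 0 can be a failed estimate, which is why such genes are called listed at 0.

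Genotype was taken from the sample titles, and sex from the labels. The labels mark the samples as separate but do not otherwise describe their origin, so p-values measure the spread between these samples. No 2 libraries held identical values, and each was counted once. All 8 columns were matched by name to a sample, and 0 columns of per-sample values were left unmapped. Symbols, gene types and coordinates came from GENCODE M21 (GRCm38), which matched 47864 IDs; 464 IDs, 29 of them tested, had no match. The table holds no counts, so the absolute depth is unknown. The most frequent ratio between libraries among very low values of long genes, where 1 fragment has the same worth per gene, gave relative depths of 1.00 to 1.31, and no interval for counting error can be given.

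The values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with terms for sex and genotype, empirical Bayes with a trend, two-sided, on genes with FPKM of 1 or more in at least 4 of the 8 libraries. Benjamini-Hochberg adjusted p under 0.05 was the threshold. The pseudocount of 1 makes fold changes of low genes smaller than the ratio of their FPKM. This left 10521 genes and 5 residual degrees of freedom. The interaction of genotype and sex label and the sex term came from the same kind of fit. Single values were compared by exact two-sided permutation tests over the 70 assignments of 4 against 4, whose smallest p is 0.0286. On simulated data for K320E-skm against wild-type, made on the 10521 genes with 100 genes changed at each size, the fit recovered 81 of 100 genes changed by 1 on the log2 scale and 97 of 100 changed by 2, with 8 false calls. The simulated genes were drawn independently, without shifts shared by a library. These rates therefore need not hold for the real libraries. Tables were read with pandas 2.3.3 in Python 3.11.15 and figures drawn with matplotlib 3.10.9.

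There were 48 gene lists covering mitochondrial, metabolic, stress, fibre type, signalling and cell type genes, of which 47 were tested and 1, of sex-linked genes, was used to check labels. Lists were tested with camera, part of limma, against the other tested genes, with a preset correlation of 0.01 between genes, adjusted over the 47 lists. The same test with an estimated correlation, fry, and an exact permutation of the mean list value per library were alternatives. For the permutation, the median over all tested genes of a library was subtracted from the mean of the list in that library. Members were also counted after adjustment over the list alone. Some genes stand in several lists, such as Mt1, Mt2, Cdkn1a, Pdk4, Casq1 and Pvalb.

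The genes named were set by a rule. They were Twnk; up to 12 rises and 12 falls past the threshold without overlap; of each list, up to 4 members past the threshold or, where none passed, up to 2 with the highest mean FPKM, with lists that were not called summarised without names; up to 4 sex-linked genes; and, with fewer than 10 genes past the threshold, the 10 with the smallest p. Predicted and small RNA genes were to be counted and not named. Some members that this rule would name are not reported here and were left out of the single-gene outlier and sensitivity counts. Members past the threshold adjusted over the list alone, Fgf21, Gdf15, Asns, Trib3, Slc7a11, Trim63, Fbxo32, the immunoglobulin genes, the genes of the sex comparison and the 4 called small RNA genes were named after their values were seen.

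The groups, the tests, the lists, the rule for named genes and most alternatives were fixed before the data were examined. Those alternatives were a pseudocount of 0.1, no filter, a filter of 5 FPKM, median-ratio rescaling, quantile normalization, no sex term, the replicate number as a block in place of the sex term, robust empirical Bayes, array weights, a minimum log2 fold change of 1, leaving out each library in turn, an estimated correlation and fry. Protein-coding genes alone, genes listed at 0 left out, and the exact permutation of list values were chosen after seeing the data.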

Results

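Total RNA from the tibialis anterior, a fast muscle of the lower hindlimb, was sequenced in 8 C57BL/6J mice at an age of 24 months. In K320E-skm mice, skeletal muscle carries a dominant mutant form of Twinkle, the helicase of mitochondrial DNA replication that is encoded by Twnk, and mitochondrial DNA alterations build up with age. The question was how muscle with this mutant protein differs in old age from wild-type muscle. There were 4 K320E-skm and 4 wild-type libraries, and in each genotype 2 were labelled male and 2 female. FPKM summed to between 731824 and 858029 per library, and 10167 to 11581 genes reached 1 FPKM. The files hold no read counts, so the absolute depth is unknown. The smallest values gave relative depths between 1.00 in K320E-skm 4 and 1.31 in wild-type 3. Pearson's r between libraries, across genes, lay between 0.940 and 0.970, and no 2 libraries held identical values.

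Twnk (ENSMUSG00000025209, a protein-coding gene on chromosome 19, 45005663 to 45012762, GRCm38) was measured first, since it encodes Twinkle, the protein whose mutant form K320E-skm muscle carries. Its level was 3.82, 4.93, 5.06 and 4.66 FPKM in K320E-skm 1 to 4 and 2.16, 2.40, 2.21 and 2.70 FPKM in wild-type 1 to 4. The means were 4.62 ± 0.557 and 2.37 ± 0.245 FPKM (SD, n = 4 each), a 1.95-fold ratio, and all 4 K320E-skm libraries lay above all 4 wild-type libraries (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 allows). FPKM per gene do not separate the transcript of the introduced copy from that of the endogenous gene. Of the loci related to the construct, Gt(ROSA)26Sor, the non-coding gene at the Rosa26 locus (chromosome 6, 113067428 to 113077333), was at 1.29 ± 0.276 FPKM in K320E-skm and 2.1 ± 0.534 in wild-type muscle (n = 4 each, exact permutation p = 0.0286). Both genes were past the threshold adjusted over the list alone, among the 5 tested genes of that list. The call of Gt(ROSA)26Sor was lost after median-ratio rescaling, where its log2 fold change went from −0.43 (SE 0.15) to −0.32 (SE 0.17), with an adjusted p of 0.155 over the list alone.

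**Figure D1:**
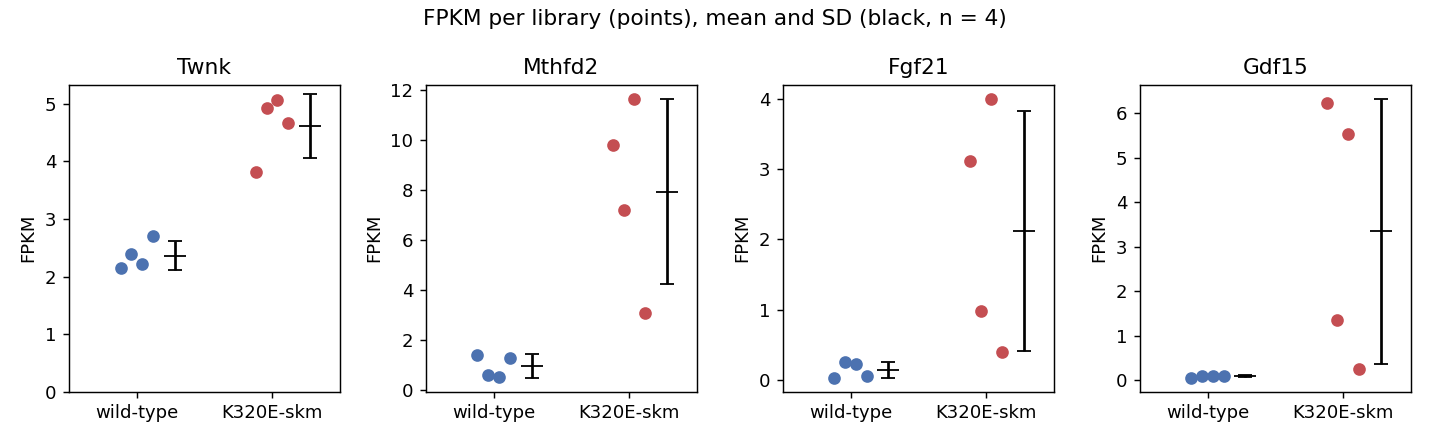
FPKM of Twnk, Mthfd2, Fgf21 and Gdf15 in each library (points, wild-type in blue and K320E-skm in red), with mean and SD in black (n = 4). In all 4 panels every K320E-skm library lies above every wild-type library, with Twnk means of 4.62 against 2.37 FPKM.

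The first comparison was K320E-skm against wild-type muscle over all genes. The folate enzyme Mthfd2, which works in mitochondrial one-carbon metabolism, averaged 7.92 ± 3.71 FPKM in K320E-skm and 0.941 ± 0.465 FPKM in wild-type muscle (n = 4 each). Prkag3, the muscle-specific gamma subunit of AMP-activated protein kinase, averaged 11.4 ± 4.38 against 22.3 ± 6.53 FPKM. Rfxap, a subunit of the complex that drives transcription of MHC class II genes, averaged 3.15 ± 0.752 against 5.71 ± 1.18 FPKM. Neither these nor any other protein-coding gene passed the threshold of limma over all genes, where the smallest adjusted p of a protein-coding gene was 0.143.

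Among 10521 tested genes, 9606 of them protein-coding, limma called 1 gene higher and 1 lower. Both are short RNA genes, named here because they were the only calls and chosen after their values were seen. Gm24157 (annotated as a miRNA gene, chromosome 11, 52099043 to 52099153) was at 51.2, 31.4, 15.6 and 30.4 FPKM in K320E-skm 1 to 4 and was listed at 0 in all 4 wild-type libraries (adjusted p = 7.68e-05). Gm25852 (annotated as a snoRNA gene, chromosome 6, 97547438 to 97547567) was at 14.0, 3.4, 7.21 and 4.46 FPKM in wild-type 1 to 4 and was listed at 0 in all 4 K320E-skm libraries (adjusted p = 0.00603). An exact 0 in this table can be a failed estimate. Myh4, the myosin heavy chain of the fastest fibres, was listed at 0 in K320E-skm 2, 3 and 4 and in wild-type 4, and at 2965 to 4357 FPKM in the other libraries. Of the tested genes, 91 had a 0 in at least 1 library, 5 of them protein-coding.

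With so few calls, the 10 genes with the smallest p are given, none of which passed. Their log2 fold changes on the scale of log2(FPKM + 1) were 2.11 for Mthfd2 (SE 0.32) and 0.74 for Twnk (SE 0.11). The other 8 were lower in K320E-skm muscle. The values were −0.69 for Rfxap (SE 0.10), −0.94 for Prkag3 (SE 0.14), −0.77 for Arhgap20 and −0.97 for the membrane protein gene Tmem233. They were −0.86 for Sorbs2, an adaptor at the Z-disc, −0.84 for Ky, a muscle protein whose loss causes kyphoscoliosis in mice, −0.79 for the secreted chaperone Clu and −0.60 for the synaptic scaffold Dlg4. Adjusted p from limma ran from 0.143 for the first 4 to 0.289. In all but Ky the 4 libraries of one genotype lay apart from the 4 of the other (exact permutation p = 0.0286, and 0.0571 for Ky). The genes were chosen by their p in the same libraries, so this separation is no further support. It held for 1044 tested genes. Without K320E-skm 4, Mthfd2 passed with a log2 fold change of 2.46 (limma adjusted p = 0.0122).

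Across the tested genes, 1383 had an unadjusted p under 0.05, where 526 would be expected by chance, and 1265 of these were lower in K320E-skm muscle against 118 higher. This split depended on how the libraries were scaled. The median log2 fold change was −0.14 as deposited and 0.00 after median-ratio rescaling, which gave 1036 such genes, 546 higher and 490 lower. Quantile normalization gave 1051, 508 higher and 543 lower. Both methods bring the libraries to a common level. A median near 0 and a near-even split largely follow from that and do not show the source of the shift. Relative to the median gene, log2 fold changes were 2.25 for Mthfd2, 0.88 for Twnk, −0.55 for Rfxap and −0.80 for Prkag3. As deposited, the genotypes did not overlap for 1044 genes, or 9.92% of those tested, where chance gives 2.86% on average. This share was not counted after rescaling or over other splits of the libraries, so chance cannot be excluded for it.

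The second comparison asked which fixed groups of genes stood above or below the other tested genes. The list ranked furthest above the other genes was that of the stress response that follows mitochondrial damage, made up of ATF4 targets and enzymes of serine and one-carbon metabolism. Its 20 tested members had a median log2 fold change of 0.48, and 19 lay above the median gene (camera adjusted p = 3.65e-22; adjusted p = 0.614 with an estimated correlation). Genes of protein synthesis and folding, atrophy, slow fibres and macrophages also stood above the other genes, and fast fibre genes below them. Of 47 lists tested, camera with its preset correlation called 22 higher and 1 lower. None of these calls held with an estimated correlation, where the smallest adjusted p was 0.614. Counted per gene, no list member passed over all genes tested, and 18 lists had a member past the threshold adjusted over the list alone.

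In the stress response list, 5 members were past the threshold adjusted over the list alone, all higher, and 15 were not. They were Mthfd2, Psat1 of serine synthesis with a log2 fold change of 0.97 (2.32 ± 1.19 against 0.656 ± 0.550 FPKM, n = 4 each), and the stress-induced transcription factors Cebpb at 0.71 (24.4 ± 5.87 against 14.2 ± 1.15 FPKM), Atf5 at 0.71 (14.9 ± 4.12 against 8.64 ± 2.27 FPKM) and Ddit3 at 0.57. Psat1 and Atf5 overlapped between the genotypes (exact permutation p = 0.0857 and 0.0571), while Mthfd2 and Cebpb did not. Atf4 itself and Vldlr, the members with the highest FPKM, had values of 0.03 and −0.16. After rescaling, 11 members passed over the list alone, all higher. Relative to the median gene of each library, the mean of the list was higher in all 4 K320E-skm libraries (exact permutation p = 0.0286, adjusted over the lists 0.224). In all, 6 lists reached this smallest p. The others were heat shock and endoplasmic reticulum stress, atrophy, aminoacyl-tRNA synthetases, apoptosis and p53 targets, and biogenesis regulators. For the stress response list, K320E-skm 4 was the library of its genotype closest to wild-type muscle. Leaving out 1 library at a time gave between 1 stress response member past the threshold adjusted over the list alone, without K320E-skm 3, and 10 members, without K320E-skm 4.

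A further 11 members of this list were below the expression filter and 1 was not analysed here. The hormones Fgf21 and Gdf15, secreted from muscle under mitochondrial stress, were among them, and were picked out after their values were seen, as were the other genes of this paragraph. Fgf21 was at 3.11, 0.976, 4.00 and 0.397 FPKM in K320E-skm 1 to 4 (mean 2.12 ± 1.71) and averaged 0.141 ± 0.113 FPKM in wild-type muscle (n = 4). Gdf15 was at 6.22, 1.36, 5.54 and 0.257 FPKM in K320E-skm 1 to 4 (mean 3.34 ± 2.97) and averaged 0.0895 ± 0.0205 FPKM in wild-type muscle. Asparagine synthetase, Asns, averaged 3.89 ± 2.78 against 0.607 ± 0.153 FPKM and the pseudokinase gene Trib3 2.59 ± 1.56 against 0.363 ± 0.230 FPKM. The cystine transporter gene Slc7a11 averaged 0.314 ± 0.242 against 0.0454 ± 0.0347 FPKM. These 5 of the 11 were higher without overlap, each at an exact permutation p of 0.0286 (n = 4 per genotype), which became 0.0629 after adjustment over the 11. With no filter, limma gave adjusted p of 0.518 for Fgf21 and 0.524 for Gdf15.

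**Figure D2:**
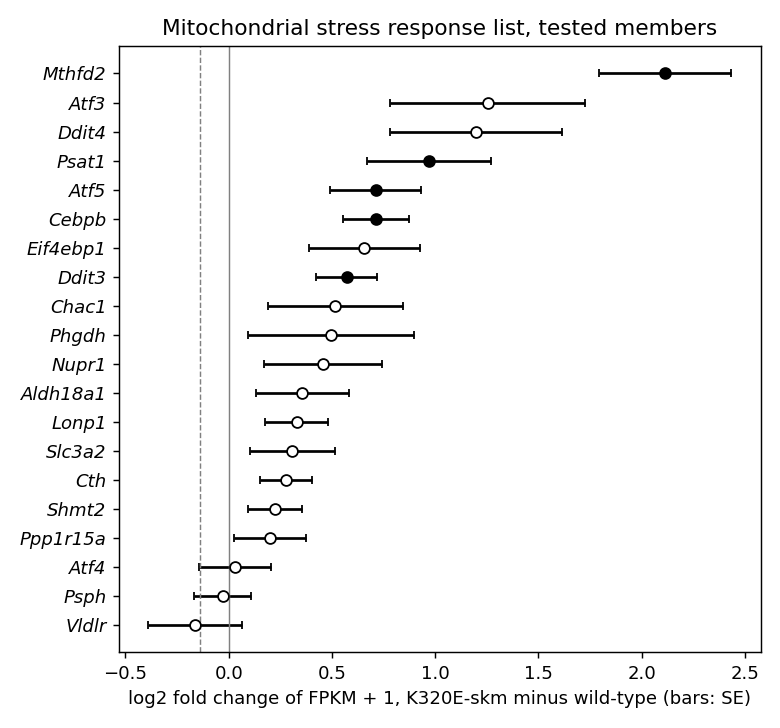
Log2 fold change of FPKM + 1 (K320E-skm minus wild-type, n = 4 each) with SE for the 20 tested members of the mitochondrial stress response list; filled points passed adjusted over the list alone and the dashed line marks the median gene at −0.14. Mthfd2 leads at 2.11, and 19 of 20 members lie to the right of the dashed line.

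Genes of protein synthesis and folding stood above the other genes. Cytosolic ribosomal proteins had a median log2 fold change of 0.07 over 50 members (camera adjusted p = 2.13e-09; adjusted p = 0.703 with an estimated correlation), with Rplp1 at 0.06 and Rpl13a at 0.09. The mean of this list relative to the median gene of each library overlapped between the genotypes (exact permutation p = 0.0857). Cytosolic aminoacyl-tRNA synthetases had a median of 0.09 over 18 members (camera adjusted p = 5.04e-06; 0.669 with an estimated correlation), with Eprs at 0.10 and Sars at 0.44. Heat shock and endoplasmic reticulum stress genes had a median of 0.09 over 29 members (camera adjusted p = 1.17e-08; 0.669 with an estimated correlation), with the chaperones Hspa8 at 0.16 and Cryab at 0.29. No member of these 3 lists passed over the list alone. After rescaling the medians were 0.25, 0.26 and 0.26, and 4 synthetases and 2 heat shock or endoplasmic reticulum genes passed, all higher.

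Muscle wasting and related metabolic genes stood above the others, with most members of each list above the median gene and large differences for a few. In the atrophy list (29 tested, median 0.04, camera adjusted p = 1.96e-07; adjusted p = 0.614 with an estimated correlation), 4 members were past the threshold adjusted over the list alone, all higher, and 25 were not; after rescaling 10 were, all higher. The 4 were the metallothioneins Mt2 with a log2 fold change of 1.84 (42.6 ± 19.0 against 10.8 ± 5.56 FPKM, n = 4 each) and Mt1 at 1.48 (65.3 ± 27.7 against 22.1 ± 9.94 FPKM), Pdk4, a kinase that restrains glucose oxidation, at 0.87 (107 ± 48.6 against 58.2 ± 27.7 FPKM) and the cell cycle inhibitor Cdkn1a at 0.75 (8.67 ± 3.33 against 4.78 ± 2.05 FPKM). All 4 overlapped between the genotypes (exact permutation p = 0.0571 for Mt2 and for Mt1, 0.143 for Pdk4 and 0.0857 for Cdkn1a). The ubiquitin ligases of atrophy were picked out after their values were seen: Trim63 averaged 103 ± 61.3 against 58.1 ± 7.31 FPKM (n = 4 each, exact permutation p = 0.0571), with 195 FPKM in K320E-skm 2, and passed over the list alone only after rescaling (adjusted p = 0.0469). Fbxo32 averaged 28.3 ± 9.71 against 31.3 ± 4.54 FPKM (exact permutation p = 0.486). The member with the highest FPKM, Ube2b, had a log2 fold change of −0.25 (118 against 141 FPKM). Metallothioneins bind metals and respond to glucocorticoids and oxidants, and both also stood in the antioxidant list (30 tested, median −0.01, camera adjusted p = 0.00039; 0.684 with an estimated correlation), where Mt1 and Mt2 were the 2 members past the threshold adjusted over the list alone, and 4 members were after rescaling. In that list Gpx4 was at 0.29 and Txnrd1 at −0.31. In fatty acid oxidation and uptake (27 tested, median −0.03, camera adjusted p = 5.75e-05; 0.711 with an estimated correlation), Pdk4, the uncoupling protein Ucp3 at 0.81 (58 ± 21 against 31.9 ± 8.82 FPKM) and the mitochondrial thioesterase Acot2 at 0.88 (9.32 ± 3.04 against 4.48 ± 0.773 FPKM) were past it, all higher, and 4 members were after rescaling. Ucp3 overlapped between the genotypes (exact permutation p = 0.0857), as did the list mean relative to the median gene of each library (0.286). Both Pdk4 and Ucp3 differed between the sex labels, at −1.11 and −0.75, male minus female (limma unadjusted p = 0.000519 and 0.0012). Their genotype p thus rests on a sex term that used the label of K320E-skm 4, which its transcripts contradict. Fabp3 and Acadm, the most abundant members of the fatty acid list, were at −0.06 and −0.21, and its call was lost without K320E-skm 3 (adjusted p = 0.0866) or wild-type 2 (0.188). Among apoptosis and p53 targets (15 tested, median 0.14, camera adjusted p = 6.25e-05; 0.614 with an estimated correlation), the survival gene Bcl2l1 at 0.60 and Cdkn1a were past it and higher, and Ccng1 at −0.44 was past it and lower, a call lost after rescaling, at −0.26 (SE 0.13 before and 0.12 after), where 3 members were past it, all higher; Phlda3 was at 0.16. The antioxidant and fatty acid lists had medians under 0 as deposited, and of 0.16 and 0.15 after rescaling.

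Fast fibre genes ranked below the other genes and slow fibre genes above them. Of the fast fibre genes (19 tested, median −0.32), 17 were lower in K320E-skm muscle (camera adjusted p = 0.00606; adjusted p = 0.684 with an estimated correlation). After rescaling the median was −0.14. As deposited, the mean of the list relative to the median gene of each library overlapped between the genotypes (exact permutation p = 0.0857, n = 4 each). The purine nucleotide enzyme Ampd1 at −0.85 (140 ± 40.9 against 249 ± 50.5 FPKM, n = 4 each), the calcium buffer Pvalb at −0.76 and the calcium store protein Casq1 at −0.61 were past the threshold adjusted over the list alone (SE 0.20, 0.21 and 0.18), and none was after rescaling, at −0.67, −0.57 and −0.43 (SE 0.21, 0.22 and 0.18). The most abundant members Tnnt3 and Tnni2, fast troponins, were at −0.35 and −0.27. Myh4, which rests on values listed at 0, stands in this list, and the call held without genes listed at 0 (adjusted p = 0.0099). The slow fibre genes (13 tested, median 0.28) stood higher (camera adjusted p = 3.3e-05, and 0.635 with an estimated correlation). No member was past the threshold over the list alone, with Myl3 at −0.11 and Myoz2 at 0.47. Relative to the median gene of each library, the mean of this list overlapped between the genotypes (exact permutation p = 0.343, n = 4 each). The call for fast fibre genes was lost with quantile normalization (adjusted p = 0.113) and without K320E-skm 2 (0.166) or wild-type 4 (0.107).

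Genes of denervation and the neuromuscular junction (22 tested, median 0.09, camera adjusted p = 0.000133) and of satellite cells and myogenesis (25 tested, median 0.05, camera adjusted p = 0.0129) stood above the other genes, with adjusted p = 0.614 and 0.703 with an estimated correlation. Their list means relative to the median gene of each library overlapped between the genotypes (exact permutation p = 0.229 and 0.114). Hdac4 was at 0.04, and no member of the first list passed over the list alone. Sln, an inhibitor of the calcium pump, was at 0.58 but had no clear direction: its mean was lower in K320E-skm muscle (21.1 ± 8.48 against 29.3 ± 41.0 FPKM, n = 4 each), with 89.6 FPKM in wild-type 2, and its log2 fold change ran from −0.16 to 1.60 without 1 library. In the second list the perinatal myosin Myh8 was past that threshold and higher, at 1.24 (3.94 ± 2.20 against 1.04 ± 0.720 FPKM, n = 4 each), and the myogenic factor Myod1 was past it and lower, at −0.77 (3.80 ± 1.14 against 7.16 ± 1.93 FPKM). Mef2c and Myf6 were at −0.39 and −0.03. After rescaling neither gene passed over the list alone, though the values stayed large: Myh8 went from 1.24 (SE 0.31) to 1.35 (SE 0.35) and Myod1 from −0.77 (SE 0.17) to −0.62 (SE 0.14), with adjusted p of 0.0600 and 0.0587. The satellite cell list was then no longer called (adjusted p = 0.238), nor was it with no filter (0.544), a filter of 5 FPKM (0.257) or quantile normalization (0.226), or without K320E-skm 1 (0.112), wild-type 1 (0.105) or wild-type 4 (0.0769).

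Nuclear genes of mitochondrial energy metabolism had medians near 0 as deposited. The camera test placed complex IV subunits (13 tested, median 0.06, adjusted p = 0.000844), ATP synthase subunits (16 tested, median 0.02, adjusted p = 0.0114), complex I subunits (36 tested, median −0.05, adjusted p = 0.017), complex II and III subunits (14 tested, median −0.02, adjusted p = 0.027), the tricarboxylic acid cycle (24 tested, median −0.04, adjusted p = 0.0175) and mitochondrial ribosomal proteins (59 tested, median −0.06, adjusted p = 0.0337) above the other genes, whose median was −0.14. With an estimated correlation the adjusted p values were 0.703, 0.79, 0.814, 0.804, 0.814 and 0.814. The means of these 6 lists relative to the median gene of each library overlapped between the genotypes. Their exact permutation p ran from 0.171 for complex IV subunits to 0.457 for the tricarboxylic acid cycle. No member of these 6 lists passed over the list alone, and their most abundant members lay between −0.20 for Uqcrb and 0.14 for Cox6a2, with Cox8b at −0.01, Atp5b at −0.03, Atp5l at 0.06, Ndufb9 at −0.05, Ndufb8 at 0.04, Uqcr11 at 0.13, Mdh1 at 0.07, Mrpl42 at −0.10 and Mrps21 at −0.16. The complex IV call was lost with array weights (adjusted p = 0.0698) and without wild-type 2 (0.219). The other 5 calls were lost with no filter (adjusted p of 0.136 to 0.777), with array weights (0.664 to 0.946) and without K320E-skm 3, wild-type 1 or wild-type 2, and all but that of mitochondrial ribosomal proteins with quantile normalization (0.141 to 0.271). Some were also lost without K320E-skm 2 or 4, and that of mitochondrial ribosomal proteins with a filter of 5 FPKM (0.0560). After rescaling the medians of the 6 lists were 0.11 to 0.24. Biogenesis regulators (16 tested, median 0.08, adjusted p = 0.000564) and mitochondrial chaperones and proteases (15 tested, median 0.05, adjusted p = 0.00606) were also called higher, with 0.614 and 0.684 as adjusted p with an estimated correlation. The former call was lost with a filter of 5 FPKM (adjusted p = 0.277), and the latter with array weights (0.147) and without wild-type 1 (0.0663) or wild-type 2 (0.10). After rescaling 3 biogenesis regulators were past the threshold adjusted over the list alone, all higher. Among biogenesis regulators, Perm1 was at 0.13 and Prkaa2, a catalytic subunit of AMP-activated protein kinase, at −0.33; among chaperones and proteases, Hspa9 was at 0.24 and Phb at 0.08. Without wild-type 2, the direction of the camera test turned for the ATP synthase, complex I, complex II and III and mitochondrial ribosomal lists, with a mean log2 fold change that differed from that of the other genes by −0.00046 to 0.014 and adjusted p of 0.69 to 0.99.

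Macrophage and monocyte genes (19 tested, median 0.23) were all above 0 in log2 fold change and stood above the other genes (camera adjusted p = 2.91e-08; adjusted p = 0.684 with an estimated correlation), with Cd74 at 0.17 and Lyz2 at 0.38. Relative to the median gene of each library, the mean of this list overlapped between the genotypes (exact permutation p = 0.171, n = 4 each). No member passed over the list alone. Interferon and nucleic acid sensing genes (17 tested, median 0.09, camera adjusted p = 0.00036) and immediate-early genes (18 tested, median 0.03, camera adjusted p = 8.89e-05) were called higher too, with adjusted p = 0.79 and 0.684 with an estimated correlation. Their list means, again relative to the median gene, overlapped between the genotypes as well (exact permutation p = 0.4 and 0.2). Ifi27l2a was at −0.03, Dusp1 at −0.09 and Nr4a1 at 0.16. The interferon call was lost after median-ratio rescaling (adjusted p = 0.0520) and without K320E-skm 1 (0.166) or K320E-skm 3 (0.107). Lymphocyte genes (4 tested, median −1.35, camera adjusted p = 0.555) were not called, and immunoglobulin transcripts were high in wild-type 1, with Igkc at 440 and Ighm at 316 FPKM.

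**Figure D3:**
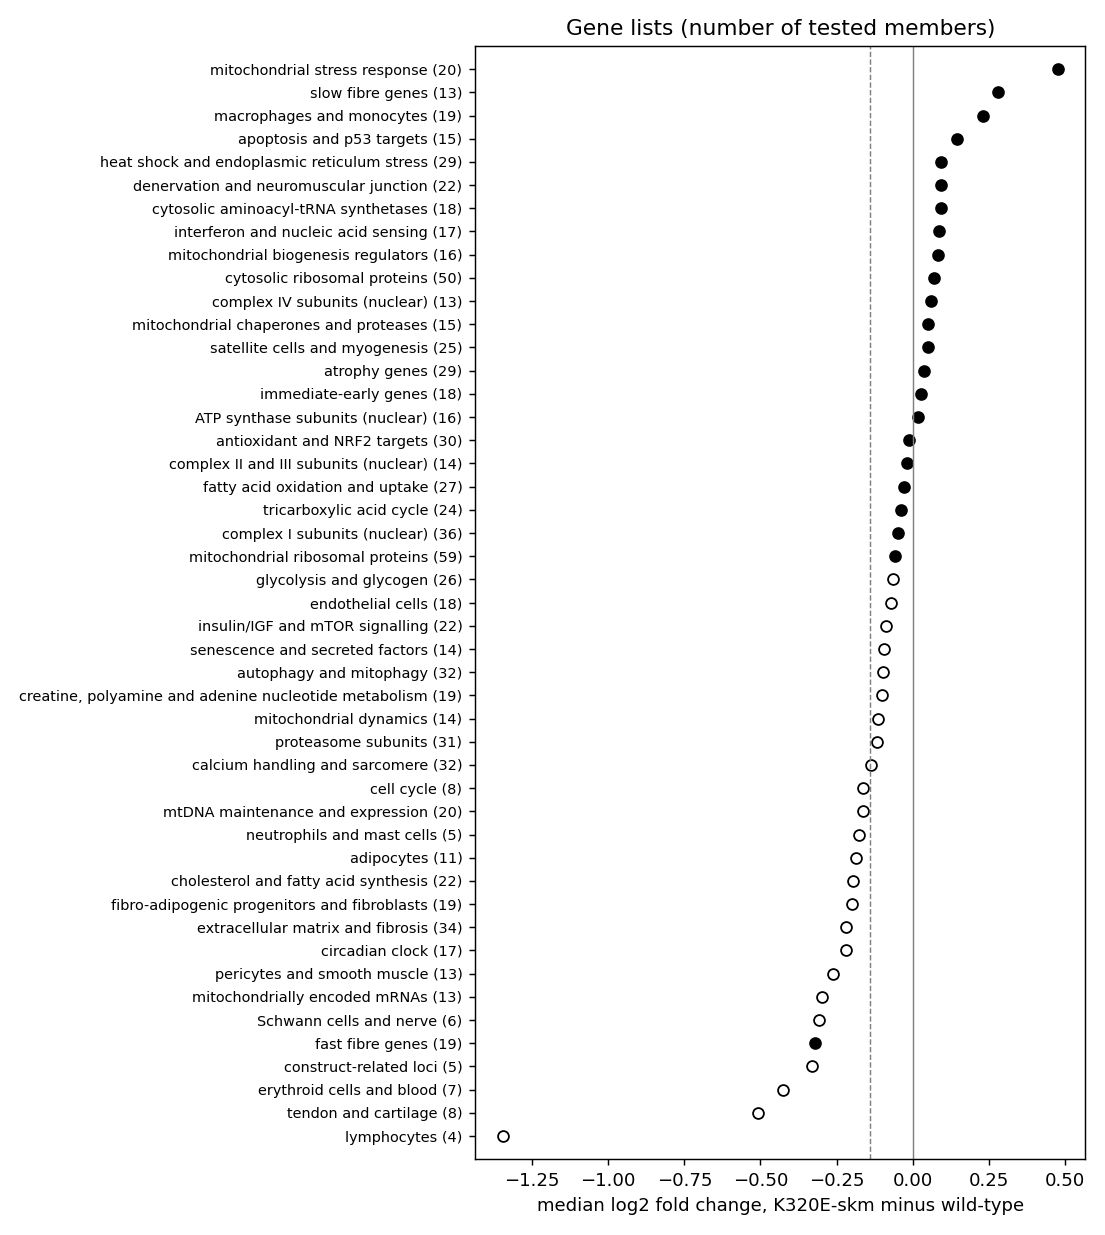
Median log2 fold change of FPKM + 1 (K320E-skm minus wild-type, n = 4 each) for each of the 47 tested lists, with the number of tested members in brackets; filled points were called by camera with its preset correlation, the solid line marks 0 and the dashed line the median gene at −0.14. The mitochondrial stress response is highest at 0.48, and fast fibre genes at −0.32 are the 1 list called lower.

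The other 23 lists were not called, besides lymphocytes. Camera adjusted p was 0.103 for senescence, 0.12 for pericytes and smooth muscle, 0.156 for erythroid cells, 0.184 for neutrophils and mast cells, 0.201 for both insulin and mTOR signalling and endothelial cells, 0.262 for glycolysis, and 0.309 for both Schwann cells and cholesterol synthesis. It was 0.338 for mitochondrially encoded mRNAs, 0.394 for creatine, polyamine and adenine nucleotide metabolism, 0.406 for mitochondrial DNA maintenance, 0.509 for autophagy and mitophagy, 0.515 for adipocytes, and 0.555 for both proteasome subunits and the loci related to the construct. It was 0.608 for extracellular matrix, 0.653 for the circadian clock, 0.668 for the cell cycle, 0.686 for calcium handling and the sarcomere, 0.757 for tendon and cartilage, 0.856 for mitochondrial dynamics and 0.885 for fibro-adipogenic progenitors. Single members of these lists were past the threshold adjusted over the list alone. In calcium handling, the Z-disc repair genes Xirp1 at 0.77 and Flnc at 0.61 were higher, and Jph1 of the triad at −0.63, Casq1 and Pvalb were lower, of which Jph1, Xirp1 and Flnc passed after rescaling too. The clock genes Arntl at −0.63, Nr1d1 at −0.52 and Bhlhe40 at −0.60, and the lipid synthesis genes Srebf1 at −0.67, Scd2 at −0.64 and Me1 at −0.60, were lower (SE 0.15 to 0.19). None of these 6 passed after rescaling, where they remained lower, from −0.35 for Nr1d1 to −0.51 for Srebf1 and Scd2 (SE 0.12 to 0.21). Others were Gdap1 of mitochondrial dynamics at −0.82 and Bpgm of red cells at −0.52, which passed after rescaling too, and Ddit4l at −0.87 and Aurka at −0.64, which did not, at −0.69 and −0.51 (SE 0.21 and 0.17 before, 0.21 and 0.18 after). Cdkn1a passed in the senescence list, after rescaling too, and Ampd1 in the adenine nucleotide list, where it did not after rescaling (adjusted p = 0.127).

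Mitochondrial ribosomal RNA held a larger share of summed FPKM in K320E-skm muscle. The 12S and 16S rRNA genes mt-Rnr1 and mt-Rnr2 together held 44.8 ± 2.54% of summed FPKM in K320E-skm and 35.4 ± 2.97% in wild-type muscle (SD, n = 4 each, exact permutation p = 0.0286). A share also depends on the rest of the sum: short RNA genes held 19.3 to 21.8% in K320E-skm and 22.3 to 29.7% in wild-type libraries, and the rRNA FPKM themselves differed by 0.31 on the log2 scale (exact permutation p = 0.0857). Weighted by gene length, which stands closer to a share of fragments, the values were 34.4 ± 3.89% and 27.3 ± 3.28%, and overlapped (exact permutation p = 0.0571). The 8 mitochondrially encoded mRNAs with high values (mt-Nd1, mt-Nd2, mt-Nd4, mt-Nd5, mt-Nd6, mt-Co1, mt-Cytb and mt-Atp8), chosen after their values were seen, held 7.11 ± 1.06% and 8.34 ± 1.63% of summed FPKM (n = 4 each, exact permutation p = 0.257). The log2 ratio of the rRNAs to these mRNAs within a library was 2.67 ± 0.296 and 2.1 ± 0.232 (n = 4 each, exact permutation p = 0.0286), with no overlap. Without mt-Atp8 it was 3.10 ± 0.258 and 2.57 ± 0.209 (exact permutation p = 0.0286). Against mt-Rnr2 alone, this ratio was higher without overlap for mt-Nd1 by 0.51, mt-Nd2 by 0.66, mt-Nd4 by 0.61, mt-Nd5 by 0.55 and mt-Co1 by 0.63 on the log2 scale (exact permutation p = 0.0286 each). It differed by 0.08 for mt-Cytb (exact permutation p = 0.6), by 0.26 for mt-Nd6 (exact permutation p = 0.343) and by 0.58 for mt-Atp8 (exact permutation p = 0.0857), with overlap in all 3. Of the 13 mRNAs, mt-Atp6 was past the threshold adjusted over the list alone, at a log2 fold change of −0.62 (SE 0.15), and lost this after rescaling, at −0.47 (SE 0.17). It overlaps mt-Atp8 and was listed at 4.91 FPKM against 14722 FPKM for mt-Atp8 in K320E-skm muscle, so the estimates of both are uncertain. The nearby genes mt-Co2 and mt-Co3 were likewise listed at only 0.981 and 1.29 FPKM in K320E-skm and 1.28 and 1.84 FPKM in wild-type muscle. How fragments were divided among these neighbours is therefore uncertain, and the ratios to mRNA and the list of 13 mRNAs rest on it.

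**Figure D4:**
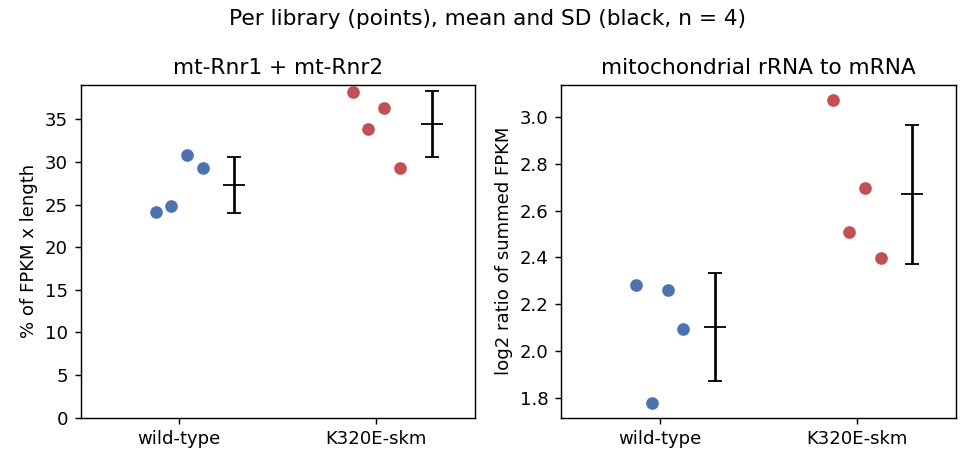
Left, share of FPKM weighted by gene length held by mt-Rnr1 and mt-Rnr2 (%); right, log2 ratio of summed mitochondrial rRNA to mRNA FPKM (8 mRNAs); points are libraries, with mean and SD in black (n = 4). The ratio is 2.67 in K320E-skm and 2.1 in wild-type muscle on average, and its values do not overlap.

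The third comparison was between the sexes, and whether the genotype difference differed between them. The sex labels did not all match the transcripts. K320E-skm 4, the library labelled male, held Xist, the transcript of the inactive X chromosome, at 10.2 FPKM and a sum of 0.0935 FPKM over the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty. The other 3 libraries labelled male held 38.7, 47.3 and 43.0 FPKM of Y-linked transcripts and at most 0.0226 FPKM of Xist. The 4 libraries labelled female held 8.82 to 15.0 FPKM of Xist and at most 0.296 FPKM of Y-linked transcripts. By these transcripts sex was not balanced between the genotypes, while every fit with a sex term used the labels. No fit with sex taken from the transcripts was run. With the labels as given, limma called 0 genes between the sexes, and 284 had an unadjusted p under 0.05. Without K320E-skm 4 it called 4: Amd1 at 1.79 and Mgst1 at 1.62 on the log2 scale, higher in libraries labelled male, and H19 at −2.04 and Xist at −3.52, lower in them.

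**Figure D5:**
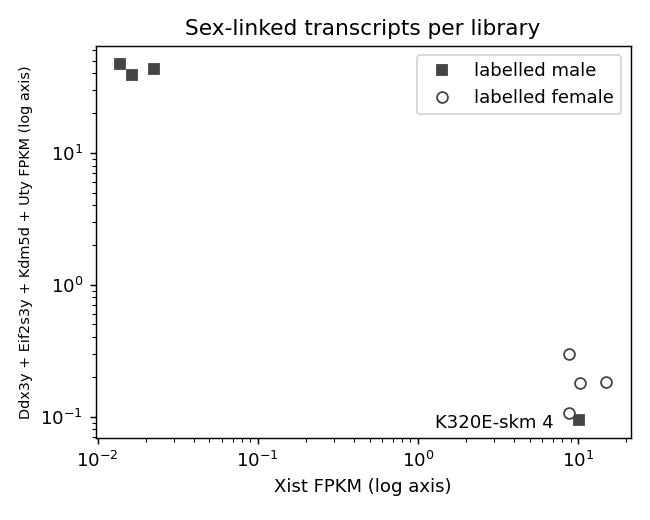
Xist FPKM (log axis) against the sum of 4 Y-linked genes in FPKM (log axis) in the 8 libraries, by sex label (squares male, circles female). K320E-skm 4, labelled male, lies with the libraries labelled female at 10.2 FPKM of Xist.

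For the interaction of genotype and sex label, limma called 2 genes, and 239 had an unadjusted p under 0.05. Both are snoRNA genes with listed zeros and were named after their values were seen. Snord65 was at 862 and 785 FPKM in K320E-skm 2 and 3 and at 839 and 1322 FPKM in wild-type 1 and 3, and was listed at 0 in the other 4 libraries (interaction adjusted p = 1.41e-08). Gm26202 was listed at 0 in K320E-skm 2 and 3 and at 2169 to 8480 FPKM in the other libraries (interaction adjusted p = 0.000143). The direction in libraries labelled male draws on K320E-skm 4, whose label the transcripts contradict. With protein-coding genes alone, the count was 0.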

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

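The tests of relative depth, of the ratio within a library, of 45S rRNA and of mRNAs that overlap no other, and all 3 tests on K320E-skm 4 were chosen only after the result was seen.

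K320E-skm 4, the library labelled male, stood apart from the other libraries labelled male with Xist at 10.2 FPKM and hardly any Y-linked transcripts. A mixture of male and female RNA is argued against by its Y-linked sum, 0.217% of the mean of the other 3 libraries labelled male. A swap with another of the 8 libraries would leave a library labelled female with Y-linked transcripts and no Xist, and 0 were found. Wild-type muscle under a K320E-skm label is argued against by Twnk at 4.66 FPKM, above the highest wild-type value of 2.70 FPKM. A single wrong sex label, or an exchange with a sample outside this series, stays open, and a biological explanation was not tested.

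Most genes at an unadjusted p under 0.05 were lower in K320E-skm muscle. The authors' scaling to all mapped fragments is a candidate explanation, since mitochondrial rRNA took a larger share of K320E-skm libraries on average. Weighted by gene length, this share was 34.4% against 27.3% and overlapped (exact permutation p = 0.0571). After scaling to the total without rRNA, the median log2 fold change was 0.01 (0.0091) in place of −0.14, and 47.2% of 722 such genes were lower. That scaling brings the remaining genes of each library to a common total. A median near 0 and a near-even split can follow from that alone, so they do not show that rRNA was the source. Wild-type 1, the library with the highest median, may account for part of the shift, since the median was −0.06 (−0.060) without it, and 1 library cannot be told apart from the genotype here. Shallower K320E-skm libraries cannot be told apart either, because relative depths overlapped but were lower in K320E-skm on average, with a log2 difference of −0.09 (−0.094, exact permutation p = 0.343). A true fall of most transcripts with genotype stays open and cannot be tested with relative values.

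Mitochondrial rRNA was higher against mitochondrial mRNA in K320E-skm muscle. Scaling between libraries cancels in this ratio, which still differed by 0.57 on the log2 scale without overlap. Fragments shared between overlapping mRNAs, as the only source, are argued against by mt-Nd1, mt-Nd2 and mt-Co1, 3 of the 4 abundant mRNAs that overlap no other mRNA, for which the ratio of mt-Rnr2 to the mRNA was higher without overlap between the genotypes. In mt-Cytb, the remaining 1, it differed by 0.08 (exact permutation p = 0.6). Fragments shared between neighbouring genes in general, tRNA genes included, cannot be told apart: the ratio was higher for 4 of the 4 mRNAs chosen beforehand (mt-Nd1, mt-Nd2, mt-Nd5 and mt-Co1), but mt-Nd5 overlaps mt-Nd6 and that choice left out mt-Cytb, and all adjoin tRNA genes. Less complete removal of rRNA might raise it too and cannot be told apart, because cytosolic 45S rRNA, which differed by 0.44 (exact permutation p = 0.686), ranged from 130 to 2224 FPKM. The genotype, whose mutant helicase acts on mitochondrial DNA, stays open as an untested biological explanation.

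Single libraries far from the other 3 of their group were found for 13 of 246 groups of values, where chance gives about 1 in 20, or 12.3. In K320E-skm 4, Xist stood out at 10.2 FPKM among the libraries labelled male. List means were taken relative to the library's median gene. The K320E-skm 4 values lower than in the other 3 were 24.0 FPKM for Mt1, 683 FPKM for Cox6a2 and 5.59 for the list mean of complex IV subunits. In K320E-skm 2 the values were 44.3 FPKM for Xirp1, 349 FPKM for Txnrd1, 53.3 FPKM for Phb, 81.0 FPKM for Phlda3, 40.1 FPKM for Dusp1 and 195 FPKM for Trim63, all higher. In wild-type 1 Scd2 was at 4.76 FPKM and Ighm at 316 FPKM, both higher, and mt-Co1 at 13931 FPKM, lower.

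The genotype difference differed between the sex labels for Snord65, with an interaction of −19.73 on the log2 scale (labelled male minus labelled female), and for Gm26202, with 10.90. Both rest on values listed at 0.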

How the results depend on the processing

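Protein-coding genes alone, genes listed at 0 left out, and the exact permutation of list values were chosen only after the result was seen; the other settings were planned. The value of a list is the mean log2 fold change of its members minus that of the other genes, and a list turned where this or the direction of the camera test did. Where no cause is named below, the cause was not tested.

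The count of genes higher in K320E-skm muscle was 1, and became 3 with array weights, where Twnk and Mthfd2 joined (adjusted p = 0.0424 each), 0 with protein-coding genes alone and 0 without genes listed at 0. The count lower was 1, and became 0 with no filter, 0 with a filter of 5 FPKM, 2 with array weights, where Rfxap joined, 0 with protein-coding genes alone and 0 without genes listed at 0. The last 2 settings remove the called genes themselves. Each count was 1 to 2 without 1 library, with 2 higher without K320E-skm 2 or 4 or wild-type 1 or 3 and 2 lower without K320E-skm 1, and Myh8 passed without K320E-skm 2 (adjusted p = 0.0257). Lists higher went from 22 to 17 with no filter, 18 with a filter of 5 FPKM, 20 with median-ratio rescaling, 17 with quantile normalization, 18 with array weights, 0 with an estimated correlation, 0 with fry and 0 with exact permutation, and to 16 to 22 without 1 library. By fry in either direction 10 lists passed. Lists lower went from 1 to 2 with no filter, 0 with quantile normalization, 2 with array weights, 0 with an estimated correlation, 0 with fry, 0 with exact permutation, and 0 to 4 without 1 library (0 without K320E-skm 2, 2 without K320E-skm 3 or wild-type 1 or 2, 4 without wild-type 3 and 3 without wild-type 4). The interaction count went from 2 to 8 with no filter, 0 with protein-coding genes alone, 0 without genes listed at 0, and 2 to 5 without 1 library (4 without K320E-skm 1 or 4 and 5 without wild-type 4). The sex count of 0 became 4 without K320E-skm 4 and 1 without K320E-skm 3 or wild-type 4, a range of 0 to 4. Adding a minimum log2 fold change of 1 left 1 gene in each direction. Array weights gave wild-type 1 the lowest weight, 0.255, and wild-type 4 the highest, 2.69.

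Replicate numbers were not taken to pair the samples, though pairing is not excluded. Deviations of same-numbered libraries correlated, across genes, at 0.156, 0.023, 0.044 and 0.040, so 1 of 4 was over 0.1. Most libraries correlated best with their own number, but K320E-skm 4 correlated best with wild-type 2, at 0.090. With the replicate block, 1 gene was higher, 1 lower and 2 lists were lower, and the other list calls did not move. The smallest adjusted p of a protein-coding gene in limma was then 0.0607. In the stress response list 9 members were then past the threshold adjusted over the list alone.

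The stress response list kept its call in every setting of the preset test. It lost the call with an estimated correlation (camera adjusted p = 0.614), with fry (0.519) and with exact permutation (0.224). No single named gene was past the threshold over all genes in the main fit, so 0 could lose a call. Of their results over all settings, 1484 kept their direction and remained not past the threshold, and 5 became past it. This count therefore does not show that any call was stable. Of called lists in the settings with the preset correlation, 379 kept both, 49 fell under the threshold in the same direction and 8 turned, none of which stayed past it. Of the 23 list calls, the fewest, 15, were kept without wild-type 2, and 16 each with array weights and without K320E-skm 3 or wild-type 1. With array weights, ATP synthase (−0.0047), complex I (−0.015), complex II and III (−0.0029) and tricarboxylic acid cycle genes (−0.0084) turned. Without 1 library, the ranges of lists that turned were 0.0061 to 0.22 for ATP synthase, 0.0028 to 0.17 for complex I, −0.00046 to 0.25 for complex II and III and 0.014 to 0.12 for mitochondrial ribosomal proteins, each lowest without wild-type 2, where the test turned.

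Named members of called lists, none of them past the threshold, changed sign 76 times, among them Sln at 0.58 and Cryab at 0.29. With median-ratio rescaling the values were 0.15 for Atp5b, 0.17 for Cox8b, 0.084 for Dusp1, 0.12 for Fabp3, 0.14 for Ifi27l2a, 0.083 for Mrpl42, 0.018 for Mrps21, 0.14 for Myf6, 0.069 for Myl3, 0.13 for Ndufb9 and 0.014 for Vldlr. With quantile normalization they were 0.21 for Atp5b, 0.18 for Cox8b, 0.071 for Dusp1, 0.010 for Fabp3, 0.097 for Ifi27l2a, 0.12 for Myf6 and 0.064 for Myl3. With array weights they were −0.058 for Atp5l, 0.0070 for Dusp1, 0.077 for Fabp3, 0.68 for Ifi27l2a, 0.091 for Myf6, −0.022 for Ndufb8, −0.041 for Perm1 and −0.0048 for Phb. Without 1 library the ranges were −0.077 to 0.18 for Atf4, −0.15 to 0.039 for Atp5b, −0.12 to 0.17 for Atp5l, −0.12 to 0.56 for Cd74, −0.17 to 0.16 for Cox8b, −0.042 to 0.58 for Cryab, −0.29 to 0.11 for Fabp3, −0.13 to 0.25 for Hdac4, −0.52 to 0.43 for Ifi27l2a, −0.067 to 0.20 for Mdh1 and −0.28 to 0.17 for Myf6. They were −0.63 to 0.43 for Myl3, −0.12 to 0.16 for Ndufb8, −0.10 to 0.028 for Ndufb9, −0.13 to 0.59 for Nr4a1, −0.023 to 0.30 for Perm1, −0.052 to 0.39 for Phlda3, −0.026 to 0.22 for Rplp1, −0.16 to 1.60 for Sln, −0.068 to 0.21 for Uqcr11 and −0.37 to 0.030 for Vldlr.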

Other observations

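The counts over other splits for genes higher, for genes lower and for the sexes, and the direction compared for lists lower, were chosen only after the result was seen; those for genes at an unadjusted p, for lists and for neighbours of the construct loci were planned.

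Further genes of muscle regeneration and denervation had no exact permutation p under 0.05, which at n = 4 and with their spread does not show that they did not differ. Pax7, the marker of satellite cells, averaged 0.108 ± 0.0822 FPKM in K320E-skm and 0.20 ± 0.117 FPKM in wild-type muscle (n = 4 each, exact permutation p = 0.257), and Myf5 0.299 ± 0.0962 against 0.304 ± 0.146 FPKM (exact permutation p = 0.943). The fusion factor Mymk averaged 0.385 ± 0.230 against 0.166 ± 0.168 FPKM (exact permutation p = 0.171) and embryonic myosin Myh3 1.5 ± 0.499 against 1.28 ± 0.893 FPKM (exact permutation p = 0.6). Of genes that rise when a muscle loses its nerve, Runx1 averaged 2.87 ± 1.25 against 2.91 ± 1.59 FPKM (exact permutation p = 0.886) and Ncam1 7.61 ± 4.71 against 5.19 ± 4.34 FPKM (exact permutation p = 0.514). The senescence gene Cdkn2a was at 0.0360 to 0.327 FPKM in K320E-skm libraries, and in wild-type muscle at 0.435 and 0.495 FPKM in wild-type 1 and 3 and listed at 0 in the other 2. These genes were picked out after their values were seen, and these p are not adjusted.

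The 8 libraries can be split into 2 groups of 4 in 35 ways. For genes higher and for genes lower, 20 of the 35 splits gave as many genes in either direction as the real 1, with 3 as the highest other, so chance cannot be excluded for either. For genes at an unadjusted p under 0.05, 2 of 35 splits gave as many as the real 1383, and the other reached 2668. That other split set K320E-skm 1, 3 and 4 with wild-type 3 against K320E-skm 2 with wild-type 1, 2 and 4. It parts the 4 libraries with the lowest median over tested genes (2.32 to 2.38 on the log2 scale) from the 4 with the highest (2.42 to 2.75). After median-ratio rescaling, a count added after the result was seen, it gave 566 such genes against 1036 for the genotypes, so its larger count followed the overall level of the libraries. Another split, K320E-skm 1 and 4 with wild-type 1 and 2 against the rest, gave the most after rescaling, 1086. Chance cannot be excluded for the count as deposited or after rescaling. For lists higher, 4 of 35 splits gave as many lists in either direction as the real 22, with 25 as the highest other. For lists lower, where the direction with fewer lists was compared, 35 of 35 gave as many as the real 1, with 11 as the highest other, so chance cannot be excluded for either. For the sexes the real count was 0, which 35 of 35 splits reach whatever the data, so the splits tell nothing here; the highest other gave 6.

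Genes near the loci of the construct and its Cre driver, Gt(ROSA)26Sor and Myl1, might differ through DNA of another strain that came with them. Of tested genes within 10 Mb, 22 of 183 (12%) had an unadjusted p under 0.05 as deposited, against 1361 of 10338 (13.2%) elsewhere (Fisher's exact p = 0.741). Such genes were thus not in excess near the loci. This does not exclude DNA of another strain as a source for single genes. Prkag3 (chromosome 1, 74738922 to 74749221) lies within 10 Mb of Myl1 (66924295 to 66945404). Bhlhe40 (chromosome 6, 108660629 to 108666925) lies within 10 Mb of Gt(ROSA)26Sor (113067428 to 113077333).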
